A study of Mus musculus with 88 samples.

How the data were processed

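Gene expression was measured by RNA sequencing in brain tissue of C57BL/6N mice aged 24 to 26 weeks whose mothers' diet had been manipulated. The 88 libraries cover 4 regions in 2 sexes. From the midbrain come the substantia nigra (SN) and the ventral tegmental area (VTA), and from the striatum its dorsal part (CPu) and its ventral part (NuAcc). Each sex and region holds 5 CC libraries, which the labels call control, and 6 CH libraries, which the labels call high fat. The groups hold different animals, and each animal gave all 4 regions. Tissue was taken between 13 and 17 h, per the labels' protocols. Total RNA was reverse transcribed with poly(T) and random primers and amplified isothermally before Nextera XT library preparation and paired-end sequencing of 100 bases, per the labels' protocols. These protocols describe a pool of 24 libraries, and how the 88 libraries were spread over pools or runs is not given in the sources used here.

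The authors deposited 8 tables, 1 per sex and region, each with 1 FPKM value (fragments scaled to transcript length and library size) for the CC group and 1 for the CH group, per the file headers. HISAT2 2.1.0, StringTie 1.3.4d, Cuffdiff 2.2.1 and the genome build GRCm38.p6 are named in the submitters' processing notes, and Ensembl release 96 in the labels' protocols. How libraries were normalized against each other is not given in the sources used here. Each deposited table also holds the authors' log2 fold change of CH over CC, a test statistic (a score with the sign of the fold change), a p-value and a q-value. Values per library were not analysed here, so the sequencing depth is unknown and no replicate could be left out, inspected or permuted. The 8 tables may have been normalized separately, and levels are compared across tables only to describe them.

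Each table has 53539 lines. Lines that repeated one locus under several identifiers with the same values were counted once, which left 51782 features, of which 17261 to 17560 per table had been tested by the authors. A gene passed when the authors' q-value was under 0.05 among tested features. These q-values had been adjusted over a larger pool than the 8 tables. The smallest q, 0.000378, belongs to the smallest p, 5e-05, and implies that 13.2% of the pool lay at that p, against 1.08% of the tested lines of these tables. The largest p with a q under 0.05 was 0.0128. Benjamini-Hochberg adjustment of the authors' p-values within each table was therefore given beside the counts per table, the list counts and the main counts of shared genes, and counts without it rest on the wider pool.

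The error printed after ± for a fold change is the fold change divided by its test statistic. The authors' p-values correspond to z values 2.27 to 2.38 times the test statistic (median per table), so a gene can pass with a fold change close to its error. The difference between sexes was tested per gene as the male minus the female log2 fold change over the root of the summed squared errors, adjusted over genes tested in both sexes. A second error, implied by the authors' p, was tried after seeing the data. On simulated SN values (16999 genes) this test recovered 43.0% of log2 differences of 2 and 86.0% of those of 4. The differences were placed in genes of at least 5 FPKM in both sexes, and the recovery holds only where the errors are as simulated. With no difference simulated 4.87% of genes had an unadjusted p under 0.05, against 0.382%, 0.531%, 0.270% and 0.320% in SN, VTA, CPu and NuAcc. The errors are therefore too wide for these data, and the simulated recovery does not carry over to them.

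There were 39 gene lists (cell types, regions of origin, pathways and complexes), fixed together with the rule for named genes before the data were examined. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 with a preset correlation of 0.01, adjusted over the lists of a table. No estimated correlation was possible, because it needs values per library. The p of a list sets its members against other genes and holds no spread between animals. The ranks of the test statistic were used in place of its values, a choice made after seeing statistics of up to 1275. In all, 34 tested features had a statistic beyond 15, and 3 of these had a q under 0.05. The error of a list's median is its standard error over members. The same test was run on the sex difference of each gene, which was added after seeing the data. It made 52 calls in 152 tests, of which 37 held with the trends below removed and 40 with a preset correlation of 0.05. Trends of fold change over transcript length and GC content were removed as an added alternative, in which lists were tested on ranks of the corrected fold changes (for the sexes, of their corrected difference over its error). They used GENCODE M21 transcripts of the same build, in which 53378 of 53472 deposited identifiers were found. On simulated data (15000 genes) trend removal took a correlation with GC from 0.854 to 0.00676.

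Named genes are the 6 largest rises and 6 largest falls per table (at least 1 FPKM in the higher group, with a gene symbol that is not a predicted one), up to 4 passing members per list, a fixed panel of 14 neuronal and glial genes, up to 12 genes passing in the same direction in at least 3 tables, and up to 4 genes per region with the smallest p for a sex difference. Alternatives were other thresholds (0.01 and 0.1), a minimum of 1 or 5 FPKM, a minimum fold of 1.5, adjustment within tables, protein-coding genes alone, other list statistics and a preset correlation of 0.05. In list tests the minimum of 5 FPKM was applied to list members as well as to the background. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.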

Results

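The dataset describes how the brains of adult offspring differed after a maternal diet manipulation. It covers the dopamine system from the midbrain, where dopamine neurons lie (SN and VTA), to the striatum, where they project (CPu and NuAcc). In each of the 8 tables a CC group of 5 mice was compared with a CH group of 6 mice of the same sex. All FPKM values, fold changes and q-values below are the authors' group values and comparisons. No spread between animals could be computed from them.

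The regions carried their known marker genes. In the authors' deposited table, Th (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128 in GRCm38), which encodes the rate-limiting enzyme of dopamine synthesis, was at 274 and 309 FPKM in the CC groups of female and male SN. The same gene was at 2.97 and 2.14 FPKM in CPu of the authors' deposited table. Drd1, the D1 dopamine receptor of striatal projection neurons, was at 106 and 120 FPKM in CPu and at 0.703 and 1.01 FPKM in SN of the CC groups in the authors' deposited table. The Y-linked gene Ddx3y was listed at 15.3 to 19.0 FPKM in CC males of the authors' deposited table and at no more than 0.00526 FPKM in CC females.

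Dopamine neuron genes fell in the SN of CH females. Of 20 dopamine neuron markers, 19 fell over all genes tested, 19 fell adjusted over the list alone, and 17 fell with adjustment within the table. The list's median log2 fold change was −1.37 ± 0.12 (cameraPR adjusted p = 2.2e-10). In the authors' deposited table Th fell from 274 to 88.9 FPKM (log2 fold change −1.62 ± 0.25). The dopamine transporter Slc6a3 fell from 303 to 101 FPKM and the vesicular monoamine transporter Slc18a2 from 96.1 to 33.4 FPKM in the authors' deposited table. The nicotinic receptor subunit Chrnb3 fell from 13.6 to 4.16 FPKM in the authors' deposited table. Markers of GABAergic midbrain neurons had a median of −0.05, with 1 of 8 higher (Pvalb, 183 to 237 FPKM) and 1 lower (Pax5, 6.56 to 4.05 FPKM) in the authors' deposited table.

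Markers of other cell types and regions changed in female SN too, most of them upward. All 10 markers of fibroblasts and meninges rose over all genes and adjusted over the list alone, 9 of them within the table (median 1.26 ± 0.09, adjusted p = 3.3e-06). Slc13a4, a sulfate transporter of this list, rose from 2.15 to 6.68 FPKM in the authors' deposited table. Of 11 cortical and pallial glutamatergic markers 7 rose (9 adjusted over the list alone, 7 within the table; median 1.29 ± 0.38, adjusted p = 0.00066), among them the vesicular glutamate transporter Slc17a7 (ENSMUSG00000070570), from 15.7 to 40.5 FPKM in the authors' deposited table. Mural cell markers (5 of 10 rose, 6 adjusted over the list alone, 5 within the table) and haemoglobin and other red blood cell genes (3 of 5 rose, 3 adjusted over the list alone, 2 within the table) were higher too, with medians of 0.78 and 0.49. Hypothalamic markers went the other way (5 of 10 fell, 6 adjusted over the list alone, 5 within the table; median −0.86 ± 0.59, adjusted p = 0.00019). Oxytocin, Oxt, fell from 21.1 to 0.676 FPKM and Pmch, the precursor of melanin-concentrating hormone, from 5.20 to 1.07 FPKM in the authors' deposited table.

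Inflammation and interferon genes rose in female SN, 9 of 16 over all genes, 9 adjusted over the list alone and 9 within the table (median 0.65 ± 0.15, adjusted p = 3.3e-06). The interferon-induced gene Ifit1 rose from 1.32 to 3.38 FPKM and complement C4b from 20.7 to 34.6 FPKM in the authors' deposited table. Gfap, the intermediate filament of astrocytes, rose from 253 to 534 FPKM in the authors' deposited table. The astrocyte list had 3 of 13 members higher (3 adjusted over the list alone, 3 within the table; median 0.17, adjusted p = 0.0012). Microglia markers had a median of 0.20 and a mean of −0.07, and the rank test pointed up (adjusted p = 0.0054), with 1 of 12 higher and 1 lower over all genes, 1 and 1 adjusted over the list alone, and 0 and 1 within the table. In total 1552 genes passed in female SN, 967 higher and 585 lower in CH, or 1067 with adjustment within the table. With list and background both limited to genes of at least 5 FPKM, the adjusted p of the pallial list was 0.0508.

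In male SN the dopamine neuron list fell as well. Of the 20 markers 17 fell (18 adjusted over the list alone, 12 within the table), with a median of −0.92 ± 0.07 (adjusted p = 1.5e-10). In the authors' deposited table Th fell from 309 to 147 FPKM (log2 fold change −1.07 ± 0.36), Slc6a3 from 349 to 158 FPKM and the nicotinic receptor subunit Chrna6 from 67.9 to 24.5 FPKM. The dopamine receptor Drd2, which dopamine neurons carry as an autoreceptor, fell from 41.7 to 22.4 FPKM in the authors' deposited table. The GABAergic midbrain list had a median of −0.15, and Six3 alone of its members passed (8.70 to 3.33 FPKM in the authors' deposited table).

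Markers of pallial neurons, meninges, blood and mural cells were higher in male SN too. Of 11 pallial markers 8 rose (8 adjusted over the list alone, 7 within the table; median 1.61 ± 0.36, adjusted p = 0.00049), with Slc17a7 from 8.23 to 43.0 FPKM in the authors' deposited table. Fibroblast and meningeal markers rose in 6 of 10 cases (7 adjusted over the list alone, 3 within the table; median 0.75 ± 0.12), and all 5 red blood cell genes rose (5 adjusted over the list alone, 4 within the table; median 1.25 ± 0.09). Of 10 mural cell markers 3 rose (3 adjusted over the list alone, 1 within the table; median 0.41, adjusted p = 0.036, and 0.058 with the length and GC trend removed). The beta-globin gene Hbb-bs rose from 131 to 287 FPKM in the authors' deposited table. Immediate early genes, which neurons switch on within minutes of activity, rose in 6 of 19 cases (6 adjusted over the list alone, 3 within the table; median 0.41 ± 0.15, adjusted p = 0.0093). Their adjusted p was 0.0681 once the trend over length and GC was removed and 0.0611 with a preset correlation of 0.05. It was 0.125 with list and background both limited to genes of at least 5 FPKM. Fold changes in this table followed GC content across genes (Spearman rho 0.516).

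In male SN 764 genes passed, 506 higher and 258 lower in CH. Adjustment within the table left 306. The adjusted p of the pallial and of the meningeal list was 0.0511 and 0.0869 with list and background both limited to genes of at least 5 FPKM. Both sexes shared 256 higher and 148 lower genes in SN, where independent lists would share 26.7 and 8.50. With adjustment within the table they shared 124 and 62. Between sexes the dopamine list differed (adjusted p = 4.8e-05), with a male minus female median of 0.38 over 20 genes and a smaller fall in males for 18 of them. It kept its call with the length and GC trend removed (median 0.25, adjusted p = 2.3e-05) and with a preset correlation of 0.05 (0.0021). For Th alone that difference was 0.55 ± 0.44 and did not pass. Inflammation and interferon genes differed as well (median −0.49, adjusted p = 0.00014, 14 of 15 lower in the male effect). Markers of other cell types moved with them. The male effect lay below the female one for fibroblasts and meninges (median −0.47, adjusted p = 0.00014), astrocytes (−0.32, 0.00014), microglia (−0.54, 3.6e-05), endothelium (−0.30, 0.00094) and mural cells (−0.25, 0.004), and above it for red blood cell genes (0.77, 0.00093).

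**Figure D1:**
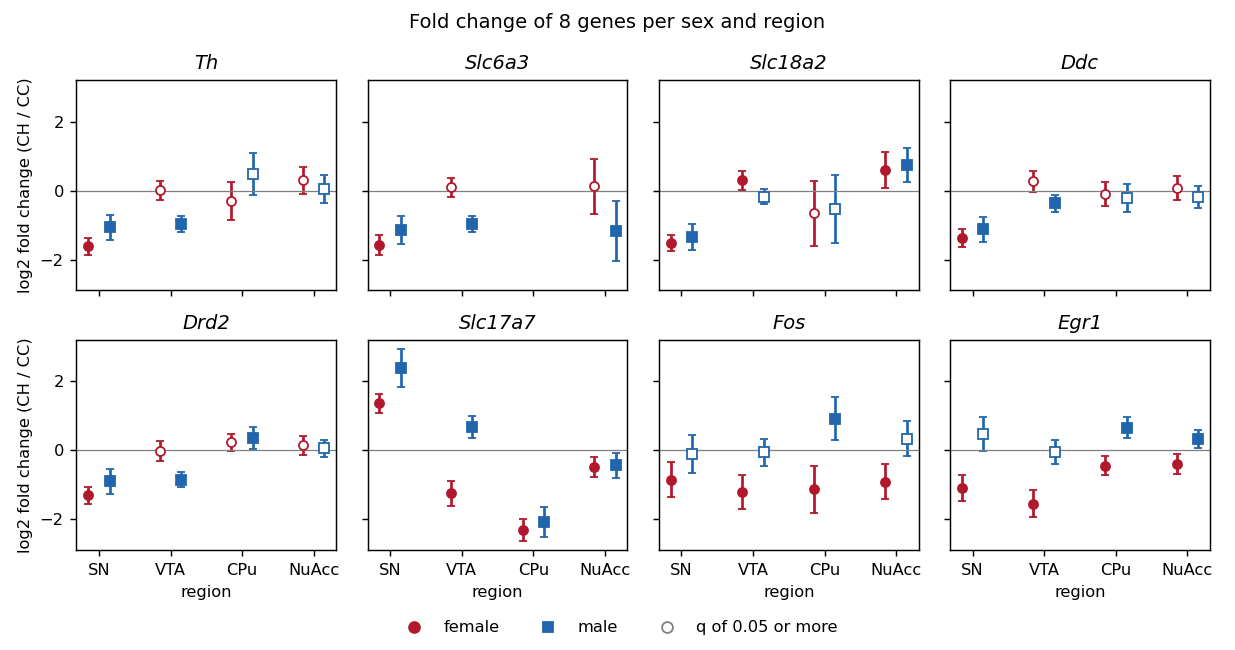
Log2 fold change of CH over CC (vertical axes) for 8 genes in each region (horizontal axes), with females as red circles and males as blue squares, from the authors' deposited table. Bars are the fold change divided by the test statistic, open symbols have a q-value of 0.05 or more, and Th lies at −1.62 in female SN, −1.07 in male SN, −0.98 in male VTA and 0.01 in female VTA.

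The VTA differed between the sexes. In CH females the dopamine list stayed near CC (median 0.02 ± 0.06, adjusted p = 0.24), with 3 of 20 markers higher over all genes, 0 adjusted over the list alone and 0 within the table. Th was at 167 and 168 FPKM and Slc6a3 at 99.7 and 106 FPKM in CC and CH of the authors' deposited table. Immediate early genes fell in female VTA, 10 of 19 over all genes, 12 adjusted over the list alone and 10 within the table (median −0.62 ± 0.23, adjusted p = 3.2e-06). The activity-dependent transcription factors Egr1, Egr4 and Fosb fell from 8.79 to 3.02, from 1.93 to 0.281 and from 2.43 to 0.790 FPKM in the authors' deposited table.

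Neuropeptide genes of the hypothalamus were lower in female VTA of CH. Of 10 hypothalamic markers 4 fell and 1 rose (4 and 1 adjusted over the list alone, 4 and 0 within the table; median −0.62 ± 0.65, adjusted p = 0.011). In the authors' deposited table Pmch fell from 13.0 to 1.59 FPKM, vasopressin, Avp, from 5.83 to 0.297 FPKM and Pomc, the precursor of melanocortins and beta-endorphin, from 28.2 to 10.8 FPKM. Slc17a7 fell from 37.9 to 16.0 FPKM in the authors' deposited table. The serotonergic list had a median of 0.36 ± 0.11 (adjusted p = 0.01), with 2 of 7 higher over all genes, 2 adjusted over the list alone and 1 within the table. Tph2, the brain's serotonin-synthesizing enzyme, rose from 61.4 to 89.4 FPKM in the authors' deposited table. Markers of other cell types moved in this table as well. Fibroblast and meningeal markers had a median of 0.43 ± 0.13 (adjusted p = 0.00044), with 2 of 10 higher over all genes, 3 adjusted over the list alone and 1 within the table. Red blood cell genes had a median of 0.58 ± 0.04 (adjusted p = 0.00091; 3 of 5 rose, 4 adjusted over the list alone, 1 within the table). Mural cell markers had a median of 0.24 with 0 of 10 passing (adjusted p = 0.00044). Lateral septal and extended amygdala markers fell in 5 of 9 cases (6 adjusted over the list alone, 1 within the table; median −0.63 ± 0.67, adjusted p = 0.0023). Cytosolic ribosomal protein genes lay above other genes (median 0.20 ± 0.02, adjusted p = 1e-09), with 0 of 21 members passing over all genes or adjusted over the list alone. Fold changes in this table fell with transcript length (Spearman rho −0.358 across genes). In female VTA 341 genes passed, 103 higher and 238 lower, or 107 with adjustment within the table.

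In male VTA the dopamine list fell, 14 of 20 over all genes, 14 adjusted over the list alone and 13 within the table (median −0.71 ± 0.12, adjusted p = 2.1e-07). Th fell from 261 to 133 FPKM (log2 fold change −0.98 ± 0.23) and Slc6a3 from 169 to 86.1 FPKM in the authors' deposited table. The transcription factors Foxa2 and Pitx3, which specify dopamine neurons, fell from 5.61 to 2.21 and from 5.09 to 2.24 FPKM in the authors' deposited table. Slc18a2 was at 94.9 and 83.5 FPKM and did not pass in the authors' deposited table. The list differed between sexes in VTA, with a male minus female median of −0.72 and 19 of 20 genes lower in the male effect (adjusted p = 1.2e-08). With the length and GC trend removed the median was −0.78 (adjusted p = 1.5e-08), and with a preset correlation of 0.05 the adjusted p was 2.1e-05. For single genes the difference was −0.99 ± 0.35 for Th and −1.22 ± 0.34 for Chrna6, and neither passed (adjusted p = 0.36 for Chrna6). With the error implied by the authors' p both passed that test (adjusted p = 0.033 and 0.0011). Fibroblast and meningeal markers differed the other way (median 0.77, 8 of 10 higher in the male effect, adjusted p = 0.0011).

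Neuropeptide genes went both ways in male VTA, where 9 of 20 fell and 3 rose (9 and 4 adjusted over the list alone, 9 and 2 within the table; median −0.44 ± 0.45, adjusted p = 0.094). Cartpt, which encodes the feeding-related peptide CART, fell from 237 to 7.35 FPKM in the authors' deposited table (log2 fold change −5.01 ± 0.36). Cholecystokinin, Cck, fell from 99.7 to 41.1 FPKM in the authors' deposited table, and Penk, the precursor of enkephalins, rose from 85.2 to 116 FPKM. Outside that list, urocortin, Ucn, fell from 22.6 to 0.627 FPKM in the authors' deposited table, and Hdc, the histamine-synthesizing enzyme, fell as well (log2 fold change −2.57). Serotonergic markers rose in 5 of 7 cases and fell in 1 (5 and 1 adjusted over the list alone, 5 and 1 within the table; median 0.70 ± 0.25, adjusted p = 0.03), with Tph2 from 79.3 to 129 FPKM in the authors' deposited table. Fibroblast and meningeal markers rose in 9 of 10 cases (9 adjusted over the list alone, 8 within the table; median 1.25 ± 0.27, adjusted p = 1.6e-05), and red blood cell genes in 4 of 5 (4 adjusted over the list alone, 3 within the table; median 0.70). A difference in the tissue dissected was not tested apart from maternal diet in VTA, for Cartpt and Ucn or for the dopamine list and its sex difference. In male VTA 724 genes passed, 367 higher and 357 lower, or 381 with adjustment within the table.

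**Figure D2:**
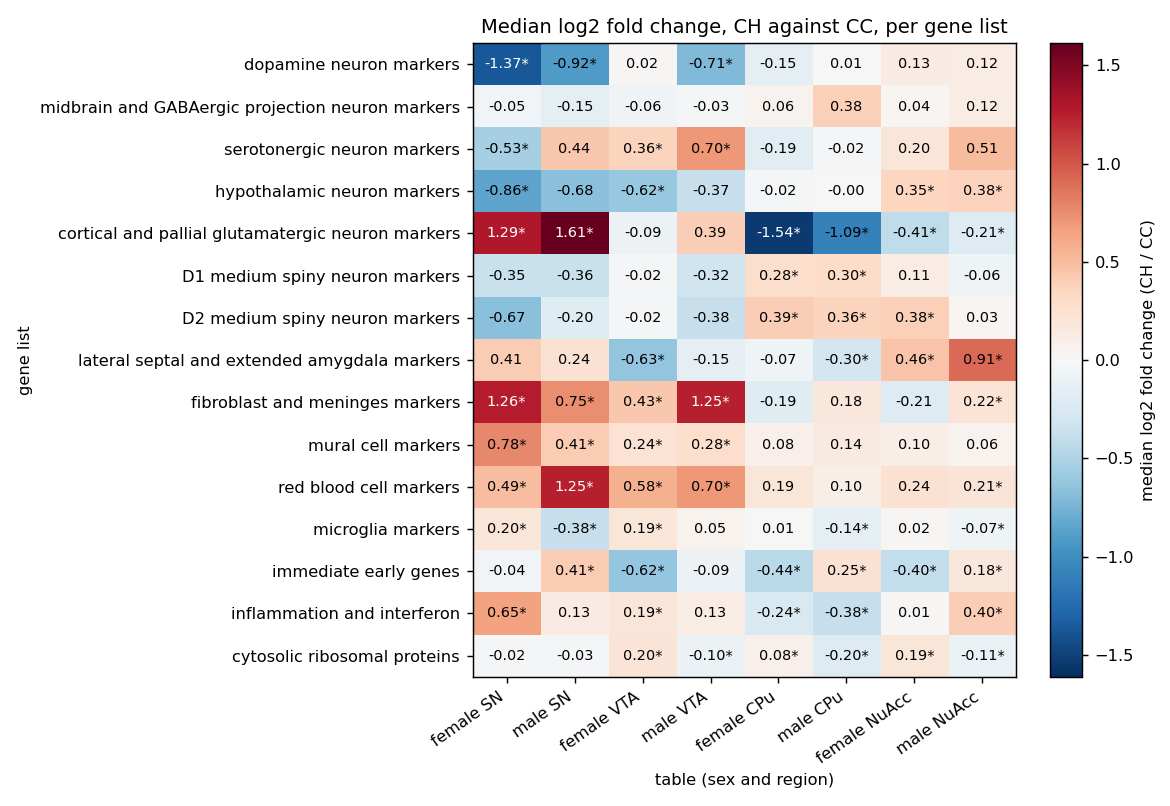
Median log2 fold change of CH over CC for 15 gene lists (vertical axis) in the 8 tables of sex and region (horizontal axis), from red for higher in CH to blue for lower. A star marks a cameraPR adjusted p under 0.05, and the dopamine list reads −1.37 in female SN and 0.02 in female VTA.

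In the CPu of CH mice, markers of cortical and pallial glutamatergic neurons were lower in both sexes. In females 8 of 12 fell over all genes, 9 adjusted over the list alone and 8 within the table (median −1.54 ± 0.36, adjusted p = 0.00043). In males 6 of 12 fell, 6 adjusted over the list alone and 5 within the table (median −1.09 ± 0.37, adjusted p = 0.0036). In the authors' deposited table Slc17a7 fell from 110 to 22.4 FPKM in females (log2 fold change −2.30 ± 0.31) and from 35.6 to 8.49 FPKM in males (−2.07 ± 0.43). The cortical transcription factor Tbr1 fell from 12.1 to 2.22 FPKM and from 3.02 to 0.649 FPKM in the authors' deposited table. Cck fell from 74.3 to 21.4 FPKM in females and from 41.7 to 16.3 FPKM in males of the authors' deposited table. Markers of striatal projection neurons of the D1 and D2 type were slightly higher, with medians of 0.28 and 0.39 in females and 0.30 and 0.36 in males. Of the 8 D1 markers 2 rose in either sex, over all genes and adjusted over the list alone (1 in females and 0 in males within the table). Of the 5 D2 markers 1 rose in either sex (4 in females and 0 in males adjusted over the list alone, 0 in either within the table). In CPu the sexes shared 92 lower genes, where independent lists would share 5.13, and 43 with adjustment within the table. With list and background both limited to genes of at least 5 FPKM, the adjusted p of the pallial list was 0.341 in females and 0.708 in males. In males the direction turned.

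Immediate early genes went apart between the sexes in CPu. In females 10 of 19 fell, 10 adjusted over the list alone and 9 within the table (median −0.44 ± 0.20, adjusted p = 5.1e-07). Fosb and Nr4a3 fell from 17.0 to 5.10 and from 7.99 to 2.08 FPKM in females of the authors' deposited table. In males 8 rose and Bdnf fell (9 and 1 adjusted over the list alone, 5 and 1 within the table; median 0.25 ± 0.24, adjusted p = 0.00099). The cytoskeletal activity gene Arc rose from 21.1 to 36.7 FPKM and Junb from 17.1 to 31.5 FPKM in males of the authors' deposited table. The list differed between sexes (male minus female median 0.87, 18 of 19 higher in the male effect, adjusted p = 8.3e-08). With the length and GC trend removed the median was 0.72 (adjusted p = 1.1e-07), and with a preset correlation of 0.05 the adjusted p was 6e-05. Ribosomal protein genes differed as well (median −0.28, 0 of 21 higher in the male effect, adjusted p = 7.4e-09; −0.19 and 3.4e-07 with the trend removed). Microglia markers differed too (−0.15, adjusted p = 0.019; 0.088 with the trend removed).

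Synaptic vesicle genes and some lipid genes fell in female CPu. In females 7 of 16 synaptic vesicle genes fell (8 adjusted over the list alone, 3 within the table; median −0.28, adjusted p = 2e-05), among them the synaptic membrane protein gene Stx1a, from 38.8 to 20.8 FPKM in the authors' deposited table. Cholesterol synthesis and lipid uptake genes fell in 5 of 21 cases (5 adjusted over the list alone, 5 within the table; median −0.22, adjusted p = 6.1e-05), with Sqle, squalene epoxidase, from 15.7 to 10.5 FPKM in the authors' deposited table. Neither list passed in males (medians 0.09 and 0.05, adjusted p = 0.35 and 0.55), and both differed between sexes (male minus female medians 0.36 and 0.24, adjusted p = 1.5e-06 and 0.00017). Stx1a itself passed as lower in male CPu too, so it does not share the contrast of its list. The inflammation and interferon list was lower in both sexes and did not differ between them (male minus female median −0.10, adjusted p = 0.423). In males 6 of 16 members fell (6 adjusted over the list alone, 2 within the table; median −0.38 ± 0.27, adjusted p = 0.00022), with the interferon-induced gene Isg15 from 11.1 to 5.01 FPKM in the authors' deposited table. The same list in females had a median of −0.24 ± 0.21 (adjusted p = 0.014), with 1 of 15 members lower over all genes, 1 adjusted over the list alone and 1 within the table. The interferon-induced genes Isg15, Ifit1 and Ifit3 did not fall in females. Their log2 fold changes were 0.05, 0.03 and 0.20 in females and −1.15, −0.67 and −0.70 in males, and none of these differences passed. In female CPu 765 genes passed, 145 higher and 620 lower, or 371 with adjustment within the table (36 and 335). In male CPu 300 passed, 148 higher and 152 lower, and 89 with adjustment within the table (20 and 69), so that the share of higher genes went from 49.3% to 22.5%.

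In the NuAcc of CH females immediate early genes fell, 9 of 19 over all genes, 9 adjusted over the list alone and 5 within the table (median −0.40 ± 0.12, adjusted p = 2e-06). Fos and Fosl2 fell from 8.96 to 4.78 and from 10.4 to 4.46 FPKM in the authors' deposited table. Pallial markers fell in 5 of 12 cases and rose in 1 (7 and 1 adjusted over the list alone, 3 and 1 within the table; median −0.41 ± 0.14, adjusted p = 0.0024), with Slc17a7 from 72.8 to 52.3 FPKM in the authors' deposited table. Neurotensin, Nts, rose from 23.4 to 41.6 FPKM in the authors' deposited table. Some of the steepest falls were of single genes, with Dmxl1 from 334 to 5.78 FPKM and the semaphorin receptor Nrp1 from 77.3 to 5.48 FPKM in the authors' deposited table. For both genes the female CC value stood far above those of the other NuAcc groups, males included (means over both sexes and groups 89.8 and 23.8 FPKM). Whether single CC libraries carried it could not be inspected. The mitochondrial gene mt-Nd3 fell from 1134 to 423 FPKM in the authors' deposited table. Ion channel genes (7 of 35 fell, 7 adjusted over the list alone, 1 within the table; median −0.22, adjusted p = 0.00037) had an adjusted p of 0.449 after the length and GC trend was removed. Fold changes fell with transcript length in this table (Spearman rho −0.468 across genes). In female NuAcc 620 genes passed, 143 higher and 477 lower, or 150 with adjustment within the table.

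In male NuAcc, lateral septal and extended amygdala markers rose, 5 of 9 over all genes, 6 adjusted over the list alone and 4 within the table (median 0.91 ± 0.23, adjusted p = 0.00095). The transcription factors Zic1 and Zic2 rose from 6.71 to 17.3 and from 1.40 to 3.71 FPKM, and the channel Trpc4 from 4.79 to 8.99 FPKM, in the authors' deposited table. Inflammation and interferon genes rose in 4 of 15 cases (4 adjusted over the list alone, 1 within the table; median 0.40 ± 0.13, adjusted p = 0.00087), with Ifit1 from 1.93 to 3.31 FPKM in the authors' deposited table. Oxt rose from 1.20 to 6.80 FPKM in the authors' deposited table. Of 19 immediate early genes 2 rose, Arc and Egr1 (2 adjusted over the list alone, 1 within the table; median 0.18 ± 0.05, adjusted p = 0.0037). Over the NuAcc the immediate early list differed between sexes (male minus female median 0.50, 19 of 19 higher in the male effect, adjusted p = 1.4e-08). With the length and GC trend removed the median was 0.54 (adjusted p = 2.4e-09), and with a preset correlation of 0.05 the adjusted p was 2e-05. Ribosomal protein genes (median −0.31, 0 of 21 higher, adjusted p = 3.6e-10) and genes of oxidative phosphorylation (−0.23, 0 of 20, 9.7e-07) differed the other way, and kept their calls with the trend removed (medians −0.12 and −0.08). Length trends were opposite in the sexes (Spearman rho −0.468 in females, 0.175 in males). Cell type markers differed there too, with fibroblasts and meninges (0.46, 8 of 9 higher, 0.018) and thalamic and midbrain glutamatergic neurons (0.30, 7 of 8, 0.018) higher and D2 neurons (−0.36, 0 of 5, 0.0093) lower in the male effect. In male NuAcc 269 genes passed, 200 higher and 69 lower, or 83 with adjustment within the table.

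Immediate early genes differed between sexes in the midbrain too, with male minus female medians of 0.43 in SN (18 of 19 higher, adjusted p = 1.1e-05) and 0.75 in VTA (15 of 19, adjusted p = 0.00056). With the trend removed the adjusted p was 2.3e-05 and 0.00078, and with a preset correlation of 0.05 it was 0.0013 and 0.014. In VTA ribosomal protein genes (median −0.30, 0 of 21 higher in the male effect, adjusted p = 7.4e-10) and microglia markers (−0.12, 0.017; 0.068 with the trend removed) differed as well, and fold changes followed length in opposite directions (rho −0.358 in females, 0.131 in males). In female SN the list itself did not pass (5 fell and 1 rose over all genes, adjusted over the list alone and within the table; median −0.04, adjusted p = 0.165). Single genes rarely passed the test of a sex difference, 12 in SN, 12 in VTA, 14 in CPu and 13 in NuAcc. That test has errors wider than the spread of these data. Only 65, 91, 46 and 55 of the 16999, 17128, 17065 and 17170 genes had an unadjusted p under 0.05, so the small counts do not speak for equal effects. With the error that the authors' p implies the counts were 44, 134, 19 and 34.

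In total 332 genes passed in the same direction in at least 3 of the 8 comparisons, 153 higher and 179 lower. With adjustment within the table they numbered 116, 49 higher and 67 lower. Nr4a2, a transcription factor of the dopamine neuron list, and the neurotensin receptor Ntsr1 fell in 5 tables (SN and CPu of both sexes and male VTA), 4 of the 5 within the table for either gene. In CPu the pallial list fell too, and which cells these falls came from was not tested. Slc13a4 and Ptgds, which encodes a prostaglandin synthase of the meninges, rose in 5 tables (SN and VTA of both sexes and male NuAcc), and 4 and 2 of these rises passed within the table. Trem2, a microglial receptor, and the relaxin receptor Rxfp1 fell in 5 tables, 2 and 4 of them within the table. Slc17a7 fell in 5 and rose in 3, with 4 and 3 within the table. Regions of the same sex shared 890 calls in the same direction over their pairs of tables (299 with adjustment within the table), and these regions come from the same animals. Pairs differed widely. Male SN and VTA shared 125 higher and 99 lower genes, with 34 called in opposite directions. Female SN and NuAcc shared 23 and 40, with 78 called in opposite directions. Sharing did not follow the animals alone. Female SN shared 155 and 144 with male VTA, from other animals, and 48 and 36 with female VTA. Male SN shared only 29 and 20 with female VTA. Directions often turned between tables. Of 395 calls with a log2 fold change of at least 2 in size, 185 (46.8%) passed in the opposite direction in another table, against 1331 of 4914 smaller ones (27.1%). In female VTA alone the shares were 42.1% and 47.2%. Rtl8b rose in 5 tables and fell in 2, but 0 of the rises and 2 of the falls passed with adjustment within the table.

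Fold changes followed transcript GC content or length to a degree that differed between tables. Across genes, Spearman's rho with GC content ran from −0.211 in female CPu to 0.516 in male SN, and with length from −0.468 in female NuAcc to 0.260 in male CPu. Genes are not independent replicates, and no p is given. Ribosomal protein genes, which are short, had medians of 0.20, 0.08 and 0.19 in females (VTA, CPu, NuAcc) and −0.10, −0.20 and −0.11 in males. In SN the medians were −0.02 and −0.03, and the sexes did not differ (adjusted p = 0.496), although GC content was followed most closely in male SN. Of 121 list calls among 308 tests, 87 held with the length and GC trend removed, and 2 pointed the other way. The list tests rest on ranks: 2 of the 121 calls held when the values of the test statistic were used, and 97 when those values were held within 15.

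**Figure D3:**
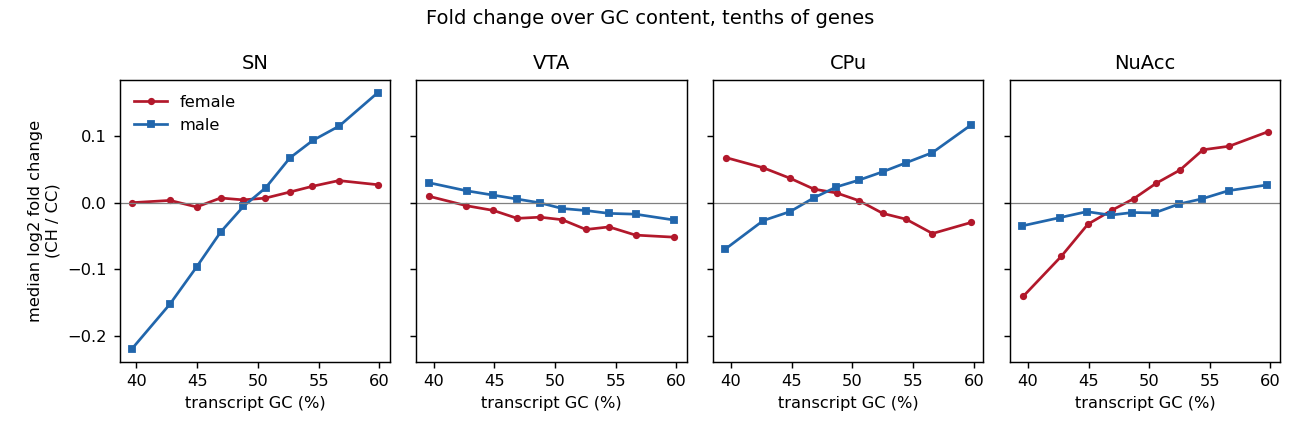
Median log2 fold change of CH over CC (vertical axis) in bins of equal size of genes ordered by transcript GC content (horizontal axis, percent), for females (red circles) and males (blue squares) in each region. In male SN the medians run from −0.22 in the bin with the lowest GC to 0.17 in the bin with the highest.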

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

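The tests of tissue share, of outside tissue and of the length and GC trend in single parts of the immediate early gene pattern were chosen only after the results were seen. The single genes first listed are those with the smallest p for a difference between the male and the female fold change in each region, among genes that passed the test of that difference.

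In SN, the male minus female log2 fold change was −4.57 ± 0.45 for Lrch1 (5.00 in females, 0.43 in males) and 10.32 ± 1.75 for Rtl8b (−2.68 and 7.63). In VTA it was −4.68 ± 0.70 for Cartpt (−0.33 in females, −5.01 in males), and a difference in the tissue dissected was not tested. In CPu it was −4.17 ± 0.37 for Rpl23a (2.47 and −1.71), −6.31 ± 0.85 for Rpl7a-ps11 (4.23 and −2.08) and −10.02 ± 1.82 for Rtl8b (7.61 and −2.41). In NuAcc it was 5.78 ± 0.36 for Dmxl1 (−5.85 and −0.07) and 4.01 ± 0.43 for Nrp1 (−3.82 and 0.20). Both rest on a female CC value far above those of the other NuAcc groups. Lrch1 had a test statistic of 30.6 in female SN and 1.03 in male SN, with a mean of 134 FPKM over both sexes and groups. Whether single libraries carried its rise could not be inspected. The rises of Rtl8b in male SN and female CPu did not pass with adjustment within the table. Small RNAs carried very large test statistics. The difference was −0.13, −1.11, 1.33 and 1.80 for the mitochondrial transfer RNA mt-Tl1 in SN, VTA, CPu and NuAcc, 1.29 for mt-Tm in VTA, and −2.23 and 2.18 for the ribosomal RNA gene n-R5s193 in VTA and NuAcc.

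Dopamine neuron markers were lower in the SN of CH mice of both sexes. A trend over transcript length and GC content is argued against as the whole cause, because the list's median nearest 0 stayed at −1.03 after the trend was removed. The GABAergic midbrain markers cannot settle whether the CH pieces held a smaller share of midbrain tissue. Their median lay above that of the dopamine list by at least 0.77 in either sex, so the lists did not fall by the same amount. But 4 of the 8 members were at 1 FPKM or more in CC of CPu in either sex. Tissue from outside the midbrain could therefore hold that median up. Tissue from outside the midbrain in place of part of the dopamine cell layer stays open, since the pallial, meningeal and red blood cell lists all had positive medians, the smallest 0.49. These lists do not mark outside tissue alone. In CC of SN all 5 red blood cell genes and 9 of 10 meningeal markers were already at 1 FPKM or more in either sex. An effect of the maternal diet on dopamine neurons stays open as well and was not tested apart from dissection or sequencing pool.

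Pallial neuron markers were lower in the CPu of CH mice of both sexes. A length and GC trend is argued against as the whole cause by a median of −1.18 after its removal, the one nearest 0. More pallial tissue, such as overlying cortex, in the CC pieces stays open, as at least 50% of the list's members fell in either sex while the D1 and D2 lists had positive medians. A maternal diet effect on these transcripts stays open and was not tested apart from dissection or sequencing pool.

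Immediate early genes were lower in CH in female VTA, CPu and NuAcc and higher in male SN, CPu and NuAcc. A length and GC trend is argued against as the whole cause where the list kept its call after the trend was removed, in the 3 female regions (median nearest 0 −0.35 ± 0.20, in CPu) and in male CPu (0.25 ± 0.24 before, 0.23 ± 0.23 after) and NuAcc (0.18 ± 0.05 before and after). In male SN it cannot be told apart, as the median went from 0.41 ± 0.15 to 0.28 ± 0.14 and the call ended with it (adjusted p = 0.068). The stricter bounds set earlier were met in neither sex. They took in female SN (−0.051) and asked for 0.3 in male SN and CPu. Female SN was not the sole shortfall, as the female CPu median of −0.35 ± 0.20 did not exceed 0.3 in size by more than its error. The argument against the trend in the regions named above therefore rests on the later test, chosen after the results were seen. A different hour of tissue collection between groups cannot be told apart in females, since the contrast of clock output genes against Arntl, at most −0.20 from 0 (NuAcc), had errors of 0.33 to 0.43. The contrast was negative in every female region and positive in every male one. In males it was 0.16, 0.14, 0.31 and 0.19 in SN, VTA, CPu and NuAcc, with errors of 0.34 to 0.46. No bound was set for males, so a different hour stays open for the difference between sexes too. A maternal diet effect that differs between sexes stays open and was not tested apart from dissection or sequencing pool.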

How the results depend on the processing

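The alternatives of a minimum of 1 FPKM, repeated lines counted as deposited, adjustment over genes of at least 1 FPKM, the error implied by p, statistics above 15, list statistics taken as values (with or without a limit of 15), removal of the length and GC trend, both alternatives for lists tested between sexes, and adjustment within the table for shared genes were chosen only after the results were seen. Of 104 counts under alternatives (passing genes, list calls and calls shared between regions), 55 stayed within 1.5 times the original and 49 moved further. Genes passing at q under 0.01 numbered 947 and 386 in female and male SN, 162 and 435 in VTA, 427 and 149 in CPu, 242 and 151 in NuAcc. At q under 0.1 they numbered 537 in female VTA, 487 in male CPu, 1024 in female and 407 in male NuAcc. With a mean of at least 5 FPKM they numbered 831 and 386 in SN, 186 and 363 in VTA, 465 and 175 in CPu, and 116 in male NuAcc. Adjustment within the table gave 306 in male SN, 107 and 381 in VTA, 371 and 89 in CPu, 150 and 83 in NuAcc, and over genes of at least 1 FPKM 935 and 268 in SN, 94 and 327 in VTA, 342 and 72 in CPu, 153 and 72 in NuAcc. With a fold of at least 1.5 they numbered 857 in female SN, 187 and 400 in VTA, 401 and 173 in CPu, 214 and 174 in NuAcc. Stricter thresholds and minimum values lower these counts by construction. Genes differing between sexes numbered 44 in SN, 134 in VTA and 34 in NuAcc with the error implied by p, and 8 in CPu and 6 in NuAcc without statistics above 15. Calls shared between regions of one sex went from 890 to 1421 (q under 0.1), 421 (at least 5 FPKM) and 299 (adjustment within the table). List tests on values in place of ranks made 2 calls where ranks made 121, because single extreme statistics widen the spread that values are tested against. With values kept within 15, 97 of the 121 held. With the length and GC trend removed 87 held and 2 pointed the other way. A preset correlation of 0.05 kept 86, and ranks of the log2 fold change kept 100. With list and background limited to at least 5 FPKM 84 held and 1 pointed the other way. Of 100 alternative tests of the lists weighed here, 77 kept their call, 22 lost it and 1 turned. The pallial list in male CPu had an adjusted p of 0.708, in the upward direction, over genes of at least 5 FPKM. That setting also drops list members under 5 FPKM, so it does not test the same list, and the cause of the turn was not tested further. For lists tested between sexes, 37 of 52 calls held with the trend removed and 40 with a preset correlation of 0.05. Of 734 values of named genes 615 passed, and 230 of these did not pass with adjustment within the table, the alternative run for them. No paired analysis was possible because the groups hold different animals and the deposited columns carry no replicate numbers. Alternatives that need values per library (other added constants, rescaling, tests on counts, leaving out single libraries, other splits of the animals, an estimated correlation) were not run, and the depth of each library, which limits what can be detected among scarce transcripts, is not given in the sources used here.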

Other observations

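All tests of gene ontology terms here were chosen only after the results were seen. In female SN the genes higher in CH held 79 of 219 tested genes of the proteinaceous extracellular matrix term, where 14.1 were expected (adjusted p = 1.5e-35). In male SN they held 38 of 214 (7.33 expected) and in male VTA 28 of 219 (5.24 expected). In female CPu the same term was enriched among genes lower in CH (31 of 207, 8.74 expected, adjusted p = 8.5e-07). Genes of neuropeptide signalling were among those lower in CH in female SN (19 of 65, 2.49 expected), female VTA (9 of 69, 1.05 expected) and male VTA (16 of 71, 1.59 expected), and among those higher in male NuAcc (7 of 68, 0.845 expected, adjusted p = 0.021). Of 19 genes of dopaminergic neuron differentiation, 9 fell in female SN (0.727 expected), 5 in male SN (0.317 expected) and 8 in male VTA (0.426 expected).

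In the striatum of males, 7 of 63 genes annotated to the response to virus were lower in CH in CPu (adjusted p = 0.0063) and 5 of 62 higher in NuAcc (adjusted p = 0.22). Of genes annotated to the cellular response to interferon-beta, 4 of 24 were lower in CPu (adjusted p = 0.053) and 6 of 23 higher in NuAcc (adjusted p = 0.00086). Neither term passed in both regions.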
